A study of Mus musculus with 2 samples.

How the data were processed

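H3K4me3 was measured by ChIP-seq in kidney tissue of B6NCrl mouse embryos of 15.5 days, with DNA fragments of 300 to 500 bp, per the labels. The series had 2 biological replicates of 1 group, replicate 1 from 78 embryos and replicate 2 from 62, each a pool of male and female embryos. The replicates were treated as separate pools, as the labels number them, and no comparison between conditions or sexes was possible.

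The authors deposited 4 peak lists on mm10, 1 for each replicate, 1 for both replicates together and 1 of replicated peaks, and all 4 were used. Per the notes deposited with the samples, each replicate's list was derived from its own filtered alignments and 1 further file, the joint list from both replicates' alignments, and the replicated list from the other 3. The aligner, the peak caller, their versions and the overlap rule behind the replicated list are not given in the sources used here. Tested on the files, all 25856 replicated peaks were identical to peaks of the joint list. Of these, 24350 shared at least 50% of either peak's bases with a peak of each replicate, and 1506 did not, so the list also holds peaks that this rule leaves out. The deposited lists hold, for each peak, a signal value, called the enrichment value here, whose scale is not given in the sources used here. They also hold the −log10 of the p of each peak, as the authors deposited it. Both are the authors' own values for each peak and were used only to describe, rank or filter peaks within a list. The design set at the outset called the first of these fold enrichment; the files do not say so, and no result needed a fold. The files give no read counts, so the depth of the libraries is unknown, and no confidence interval of a single peak's value can be given. Weak peaks near the authors' threshold are therefore the least certain calls.

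Coordinates were annotated with GENCODE M21 genes and transcripts on GRCm38, the assembly of mm10, using the 21853 protein-coding genes on assembled chromosomes and their 54361 start sites. A gene was called marked when a replicated peak overlapped the window of 1000 bp on either side of a start site of any of its protein-coding transcripts by at least 1 bp. Peaks were classed as promoter (start sites of all annotated transcripts), exon, intron or intergenic, in that order. Background shares came from 100 random placements of the peaks on their own chromosomes with a fixed seed of 20. Promoter CpG content was the observed over expected CpG ratio within 500 bp of the start site, low under 0.35 and high over 0.6. Peaks closer than 1000 bp were joined into domains, and a gene's width was that of the widest domain at its promoter. Errors are SDs of the 2 replicates' own lists (n = 2), with 0 for a replicate without a promoter peak, while widths called replicated come from the replicated list. A peak over 2 start sites marks both genes, so neighbours that share a domain were named at least once for each gene given with a width.

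There were 28 gene lists, 22 of named genes and 6 by name pattern, fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for the genes named. Each list was compared with all other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 28 lists and a threshold of 0.05. Each was also compared by a two-sided permutation test with 10000 random lists matched on deciles of promoter CpG content. These p-values compare genes within these libraries, not replicates, and genes are not independent. The median width of each list with at least 8 marked members was placed among 10000 random lists of marked genes. The text names 29 genes fixed at the outset, up to 4 widest marked members and up to 4 unmarked members in alphabetical order of each list, and every member of a side with 5 or fewer. It also names the 20 widest domains by the gene nearest their centre, the 10 peaks with the highest enrichment values, and listed genes marked in 1 replicate alone. Other genes are said to have been chosen after their values were seen.

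The list tests were tested on simulated data over 21853 genes before use. Of 200 simulated lists of 20 genes, Fisher's exact test called 200 when 20% of the genes were marked, 177 when 95% were marked and 1 when 67.2% were marked, the share of all genes. Of 400 lists of 10 genes it called 362, 16 and 0, so a list of 10 fully marked genes is close to the limit of the test. Of 50 lists chosen by CpG content alone, the test called 50, and the CpG-matched comparison called 0. A simulated list of domains made 3 times wider lay at percentile 100, and 3 of the other 49 lists lay outside percentiles 2.5 to 97.5. In the simulations with 10 or 20 genes per list, all lists tested together had the same marked share, and marks were drawn independently. The real lists mix shares, and some members share domains, so the simulated calls may overstate the power for them.

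Alternatives covered promoter windows of 500 and 2500 bp, the joint list, each replicate's list alone, the intersection of the replicates, enrichment values of at least 5, −log10 p of at least 10, peak summits, the most upstream start site, 50% reciprocal overlap, the 20000 strongest peaks, other joining distances (0 and 3000 bp) and CpG-matched lists. After the main results were seen, 24 further gene groups were tested, 6 of named genes and 18 by name pattern, of which 3 subfamilies of protocadherins were added after their members had been seen. Also added then were RefSeq start sites (GRCm38.p6), CpG islands within 10 kb (windows of 200 bp, GC fraction of at least 0.5, CpG ratio of at least 0.6) and the share of a promoter's 32-mers that occur at more than 1 place in the genome. Peaks on unplaced scaffolds were left out of the counts of promoters, since the gene tables cover assembled chromosomes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.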

Results

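H3K4me3, the trimethylated form of lysine 4 on histone H3 that marks active and poised promoters, was mapped by ChIP-seq in kidneys of mouse embryos of 15.5 days. The series had 1 group with 2 biological replicates, pools of kidneys from 78 embryos (replicate 1) and 62 embryos (replicate 2), each with embryos of both sexes. The authors' peak lists held 31076 peaks over 39.3 Mb for replicate 1 and 31019 peaks over 40.7 Mb for replicate 2. A list called on both replicates together held 33037 peaks over 44.5 Mb, and the authors' replicated list held 25856 peaks over 42.6 Mb with a median width of 1395 bp. The lists give no read counts, so the depth behind each peak is unknown. With 1 group there was no comparison between conditions, and the comparisons below are between replicates, between genes and between gene lists. All coordinates are mm10, and errors after ± are SDs over the 2 replicates (n = 2).

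The regulators of the embryonic kidney named here carried the mark in both replicates, and Six2, Pax2, Wt1 and Gata3 had domains of similar width in each. At Six2, which keeps nephron progenitors dividing, the domain was 13.6 kb in replicate 1 and 14.0 kb in replicate 2 (13.8 ± 0.291 kb). Pax2, a transcription factor of both kidney lineages, had domains of 18.8 ± 0.302 kb, and Wt1, needed for nephron progenitors and podocytes, of 12.3 ± 0.451 kb. Gata3, a transcription factor of the ureteric bud, had domains of 22.1 ± 0.816 kb, shared with 4930412O13Rik and 9230102O04Rik. Osr1, an early marker of the kidney field, differed most among the progenitor regulators named here, with 4.26 kb in replicate 1 and 8.68 kb in replicate 2 (6.47 ± 3.13 kb). Over all peaks, 86.8% of replicate 1 peaks overlapped a replicate 2 peak by at least 1 bp, and 84.2% of replicate 2 peaks overlapped a replicate 1 peak. Peaks placed at random on the same chromosomes overlapped in 2.98% and 2.95% of cases (means of 100 placements). Peaks without a partner were weak and narrow, with a median enrichment value of 2.89 and width of 228 bp in replicate 1, and 2.95 and 240 bp in replicate 2. In the quartile of peaks with the lowest enrichment values, 54.3% (replicate 1) and 46.8% (replicate 2) were shared, and in the upper 2 quartiles 100% were shared in each list. Across the 24607 regions found in both lists, the Spearman correlation of the enrichment values was 0.941; regions are not independent replicates, so no p was computed. With 50% reciprocal overlap required, the shared shares were 74.5% and 74.6%.

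Promoters held most of the mark. The 10 replicated peaks with the highest enrichment values lay at Nasp and Odf2 (each 80.6), Ssbp3 (80.2), Pip4p1, whose peak also covered the promoter of Pnp, and Zbtb11 (each 80.1), Mgea5 (79.9), Rpsa (79.7), Nup133 (79.6), Bap1 (79.5, also over the promoter of Phf7) and Thap12 (79.2). Nasp encodes a histone chaperone, Rpsa a protein of the small ribosomal subunit, Nup133 a nuclear pore protein and Bap1 a deubiquitinase. Their peaks were 2.58 to 5.87 kb wide, and their summits lay 13 to 503 bp from an annotated start site. The peak at Nasp covered chromosome 4 from 116625318 to 116628689, and the peak at Ssbp3 chromosome 4 from 106908878 to 106914745. Of the 25845 replicated peaks on assembled chromosomes, 17249 (66.7%) overlapped a window of 1000 bp on either side of an annotated start site, against 10.4% of randomly placed peaks. These promoter peaks held 85.2% of the bases under replicated peaks. A further 1513 peaks (5.85%) overlapped exons, 3130 (12.1%) introns and 3953 (15.3%) intergenic sequence, against 9.11%, 31.3% and 49.3% at random. Promoter peaks had a median enrichment value of 43.2, against 5.36 in exons, 3.99 in introns and 5.64 between genes. A protein-coding start site was present at 15789 promoter peaks, and 982 others lay at start sites of long noncoding RNAs. In the replicates' own lists the promoter share was 61.3% and 61.1% (61.2 ± 0.125%).

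**Figure D1:**
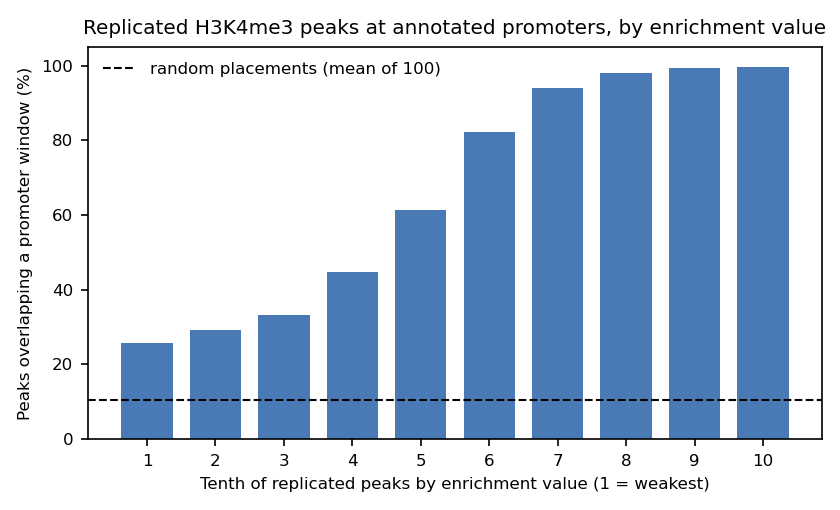
Share of replicated H3K4me3 peaks that overlapped a promoter window (y axis, percent) in 10 groups of equal size ordered by enrichment value (x axis, 1 for the weakest); the dashed line is the mean of 100 random placements. The share rose from 25.8% in the weakest group to 99.7% in the strongest.

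The mark was present at the promoters of 14674 of 21853 protein-coding genes (67.2%), among them Actb, Six2, Wt1, Ret and Foxd1 and not Alb, Umod, Slc12a1 or Pou5f1. Actb, which encodes a cytoskeletal actin, had a domain of 4.93 ± 0.692 kb on chromosome 5. Alb encodes the main serum protein made in liver, Umod a urinary protein of the thick ascending limb, Slc12a1 the salt transporter of that segment, and Pou5f1 a factor of pluripotent cells. None of these 4 had a promoter peak in either replicate. Aqp2, the water channel of the mature collecting duct, had a promoter peak of 0.310 kb in replicate 1 and none in replicate 2 or the replicated list. CpG-rich promoters were marked in 11087 of 11234 genes (98.7%), middle promoters in 2804 of 3620 (77.5%) and CpG-poor promoters in 783 of 6999 (11.2%). CpG-poor promoters with the mark included those of Hnf4a, Slc34a1, Nphs1 and Pax8. Replicate 1 marked 14711 genes and replicate 2 marked 14732, with 14609 in both, 102 in replicate 1 alone and 123 in replicate 2 alone. Marked genes made up 52.3% of the 948 genes on the X chromosome and 81.3% of the 642 on chromosome 12, the lowest and highest shares outside the Y chromosome. On the Y chromosome 4 of 183 genes were marked, Ddx3y, Uty, Eif2s3y and Kdm5d, with domains of 1.75 ± 0.269, 1.66 ± 0.0644, 1.61 ± 0.0919 and 1.16 ± 0.0170 kb; these 4 were named after their values were seen.

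Every gene of the nephron progenitor, early nephron and podocyte lists was marked, 20 of 20 in each. Members called widest in the lists below were chosen by domain width in the replicated list, and the values given are the means of the replicates, whose order can differ; Robo2, Pdgfra, Mecom, Cdk1 and Mcm5 were added after their values were seen, for their means. Among nephron progenitor genes, the widest were Hoxa11 (48.9 ± 1.90 kb) and Hoxd11 (41.2 ± 4.31 kb), which they shared with neighbouring Hox genes, then Pax2 (18.8 ± 0.302 kb) and Six2 (13.8 ± 0.291 kb, and 16.4 kb in the replicated list), with Uncx at 14.9 ± 1.44 kb and 15.5 kb. Sall1 (12.2 ± 0.472 kb), Gdnf (8.11 ± 0.584 kb), Eya1 (8.07 ± 0.0502 kb) and Cited1 (4.74 ± 0.162 kb) were also marked; Gdnf encodes the ligand that draws the ureteric bud into the progenitor field. In the early nephron list, Pou3f3 (12.5 ± 0.413 kb), Lhx1 (11.8 ± 0.885 kb), Osr2 (10.02 ± 0.0707 kb) and Jag1 (9.76 ± 0.293 kb) had the widest domains. Pax8 (5.75 ± 0.996 kb) and Wnt4 (3.81 ± 0.246 kb), both genes of the early nephron, had narrower ones. The podocyte list included Foxc2 (13.6 ± 5.77 kb, and 9.52 kb in the replicated list), Foxl1 (12.4 ± 7.397 kb, and 6.91 kb in the replicated list), Efnb2 (8.65 ± 0.130 kb), Mafb (6.74 ± 0.934 kb) and Robo2 (6.86 ± 0.206 kb). The means and SDs of Foxc2 and Foxl1 imply the same width in 1 replicate, so a single joined domain may be counted for both there. The list also held the slit diaphragm genes Nphs1 (1.21 ± 0.474 kb, shared with Kirrel2) and Nphs2 (0.596 ± 0.0509 kb). With windows of 500 bp Nphs1 was unmarked, and 95% of the list was marked. Each of these lists was marked above the 67.1% of all other protein-coding genes (Fisher's exact test, two-sided, p = 0.000484, p = 0.00136 after adjustment over 28 lists). Random lists matched on promoter CpG content were marked in 94.0%, 94.7% and 94.0% of genes, and against them the adjusted permutation p was 0.801, 0.881 and 0.576. With 20 of 20 genes marked, no higher share was possible, so this comparison could not have called these lists above the matched lists.

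Genes of the ureteric bud, the stroma and the endothelium were also marked nearly in full. The ureteric bud list had 19 of 20 genes marked, and the exception was Upk1b, which encodes a protein of the mature urothelium. Its widest domains lay over Hoxb7 (57.9 ± 0.852 kb, shared with 5 other Hoxb genes), Gata3 (22.1 ± 0.816 kb), Emx2 (14.97 ± 1.36 kb) and Crlf1 (6.74 ± 3.60 kb, shared with Tmem59l). Wnt11 (6.62 ± 0.442 kb) and Ret (3.55 ± 0.146 kb), which act at the branching tips, were marked. The stroma list had 22 of 23 genes marked, with Meis2 (19.6 ± 2.66 kb), Meis1 (14.8 ± 0.708 kb), Pbx1 (10.6 ± 0.0806 kb) and Tcf21 (9.04 ± 1.496 kb, and 11.6 kb in the replicated list) the widest there, Pdgfra at 9.33 ± 0.426 kb, Foxd1 at 6.38 ± 0.588 kb, and Ren1, which encodes renin, unmarked. All 15 endothelial genes were marked, among them Egfl7 (8.08 ± 0.634 kb), Plvap (4.78 ± 0.0601 kb), Esam (4.43 ± 0.154 kb) and the VEGF receptor gene Kdr (4.31 ± 0.112 kb). Fisher's exact test gave adjusted p = 0.0122, 0.00551 and 0.00768 for the lists. Against CpG-matched lists, marked in 83.9%, 73.8% and 73.1% of genes, the adjusted permutation p was 0.197, 0.00840 and 0.0134. The ureteric bud call ended when the peak summit had to lie in the window (80.0% marked, Fisher's exact test adjusted p = 0.335), and the endothelial call when only the most upstream start site of each gene was used (86.7%, adjusted p = 0.131).

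Genes of the mature tubule were marked in part. In the proximal tubule list 14 of 24 genes were marked, with Lrp2 (4.69 ± 0.228 kb), Hnf1a (4.43 ± 0.0170 kb), Hnf4a (2.77 ± 0.669 kb) and Ggt1 (2.32 ± 0.123 kb) the widest. Lrp2 encodes the endocytic receptor megalin, and Hnf4a and Hnf1a are transcription factors of this segment. Slc34a1, the phosphate transporter gene, had a domain of 1.64 ± 0.159 kb at enrichment values of 3.90 and 4.91 in the replicates, and Acsm2, Hao2, Kap and Miox were among the unmarked genes. In the loop of Henle and distal tubule list 13 of 20 genes were marked, with Sim1 (13.5 ± 0.151 kb), Tfap2b (7.94 ± 0.146 kb), Wnk4 (5.97 ± 1.58 kb) and Sim2 (5.38 ± 0.993 kb) the widest in the replicated list, Mecom at 5.78 ± 0.305 kb, and Clcnkb, Cldn16, Kcnj1 and Slc12a1 among the unmarked. In the mature collecting duct list 8 of 16 genes were marked, with Hsd11b2 (5.40 ± 0.252 kb), Aqp3 (3.35 ± 0.173 kb), Scnn1g (3.00 ± 0.995 kb) and Slc26a4 (1.32 ± 0.0233 kb) the widest, and Aqp2, Aqp4, Atp6v0d2 and Atp6v1b1 among the unmarked. None of the 3 lists differed from other genes by Fisher's exact test (adjusted p = 0.451, 0.815 and 0.243). The proximal tubule list lay above CpG-matched lists (58.3% against 37.1%, adjusted permutation p = 0.0448), and the other lists did not (65.0% against 62.9%, and 50% against 45.6%, adjusted permutation p = 1 for each). The matched comparison used the replicated list, in which the proximal tubule gene Cubn was marked with a peak in replicate 1 alone. In the replicates' own lists 66.7% and 54.2% of the proximal tubule genes were marked. At enrichment values of at least 5, the proximal tubule and collecting duct lists fell below other genes (33.3% and 31.3% marked, Fisher's exact test adjusted p = 0.00467 and 0.0116).

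Genes of other blood and body cell types were marked less often than the rest. None of the 14 immune genes, such as Adgre1, Aif1, C1qa and Cd19, had a replicated promoter peak (Fisher's exact test, adjusted p = 1.18e-06); C1qa had a peak in replicate 1 alone, and Csf1r, Laptm5 and Tyrobp in replicate 2 alone. In the erythroid list 5 of 15 genes were marked, Tal1 (6.60 ± 2.34 kb), Epor (3.35 ± 0.312 kb), Klf1 (2.13 ± 0.244 kb), Ank1 (1.76 ± 0.0226 kb) and Gypa (1.08 ± 0.0573 kb), while the haem synthesis gene Alas2, Epb42, Gata1 and the globin gene Hba-a1 were unmarked (Fisher's exact test, adjusted p = 0.0166). Without replicate 1 the erythroid share was 46.7% (Fisher's exact test, adjusted p = 0.141). Of 15 liver genes, Apoh (3.11 ± 0.161 kb, a domain shared with Prkca) and Trf (0.85 ± 0.392 kb, shared with Gm20425) were marked, and Afp, Ahsg, Alb and Apoa1 were not (Fisher's exact test, adjusted p = 0.000147). Gonad and adrenal genes were marked in 4 of 13 cases, Dhh (3.17 ± 2.63 kb, shared with Rhebl1), Foxl2 (2.83 ± 0.152 kb), Nr5a1 (2.48 ± 0.0113 kb) and Gata4 (1.70 ± 0.517 kb), and Amh and the steroid enzyme genes Cyp11a1, Cyp11b1 and Cyp17a1 were unmarked (Fisher's exact test, adjusted p = 0.0211). That call ended without replicate 1 (38.5%, Fisher's exact test adjusted p = 0.0539). Against CpG-matched lists, immune (0% against 18.5%), liver (13.3% against 34.1%) and gonad and adrenal genes (30.8% against 43.9%) were marked less often and erythroid genes (33.3% against 27.8%) more often, and none of these differences passed the threshold (adjusted permutation p = 0.216, 0.206, 0.317 and 1). With none of the 14 immune genes marked, no lower share was possible, and the permutation p before adjustment was 0.0772. This comparison could therefore not have called the immune list below its matched lists.

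Germ cell and sensory receptor genes were marked less often than lists matched on promoter CpG content. Of 13 germ cell genes, Dmrt1 (1.61 ± 0.0983 kb), Dazl (0.854 ± 0.126 kb) and Tdrd1 (0.462 ± 0.0226 kb) were marked; Ddx4, Mael, Piwil1 and Prm1 were among the 10 that were not (Fisher's exact test, adjusted p = 0.00312). Lists matched to them on CpG content were marked in 84.8% of genes (permutation p = 0.0002, the smallest these draws can give, adjusted permutation p = 0.00187). Of 1092 olfactory receptor genes, Olfr94 (1.06 ± 0.0679 kb), Olfr1033 (0.386 ± 0.0368 kb) and Olfr658 (0.280 ± 0.00990 kb) were marked (0.275%), against 70.7% of other genes and 8.87% of CpG-matched lists. Of 327 vomeronasal receptor genes only Vmn1r4 was marked, in a domain of 2.70 ± 1.10 kb shared with Nt5c3 (Fisher's exact test, adjusted p = 4.95e-157), against 4.24% of CpG-matched lists. Both receptor families lay below the CpG-matched lists at the smallest permutation p (0.0002, adjusted permutation p = 0.00187). Repeated promoter sequence was not measured for most of these receptor genes, and matching on deciles leaves CpG differences within a decile. In the pluripotency list 6 of 12 genes were marked, with Sall4 (2.66 ± 0.202 kb), Fgf4 (1.88 ± 1.03 kb), Lin28a (1.86 ± 1.14 kb) and Utf1 (1.22 ± 0.122 kb) the widest, and Dppa4, Dppa5a, Nanog and Pou5f1 among the unmarked (Fisher's exact test, adjusted p = 0.287, and adjusted permutation p = 0.0560 against CpG-matched lists).

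Lists of genes from other organs were marked to different degrees. All 21 genes that pattern the anterior nervous system were marked, with Emx1 (6.32 ± 0.0573 kb), Pax6 (4.44 ± 0.207 kb), En2 (4.09 ± 0.104 kb) and Dlx2 (3.56 ± 1.09 kb) the widest (Fisher's exact test, adjusted p = 0.00116). At enrichment values of at least 5, 85.7% remained marked and the call ended (Fisher's exact test, adjusted p = 0.0785). Neuron and neural crest genes were marked in 13 of 16 cases, with Hand2 (4.42 ± 2.59 kb), Ascl1 (3.20 ± 0.306 kb), Elavl4 (2.56 ± 0.0297 kb) and Snap25 (2.49 ± 0.00707 kb) the widest, and Dbh, Phox2b and Th unmarked (Fisher's exact test, adjusted p = 0.358). In the heart list 8 of 14 genes were marked, with Gata6 (10.2 ± 1.76 kb), Ryr2 (2.19 ± 0.272 kb), Hand1 (1.949 ± 0.703 kb) and Tbx20 (1.21 ± 0.0460 kb) the widest, and the contractile and hormone genes Myh6, Myh7, Myl7 and Nppa among the unmarked (Fisher's exact test, adjusted p = 0.458). Gut and pancreas genes were marked in 9 of 15 cases, with Nkx6-1 (4.06 ± 1.36 kb), Lgr5 (3.396 ± 0.143 kb), Sox2 (2.63 ± 0.217 kb) and Ptf1a (1.33 ± 0.0969 kb) the widest, and the gut gene Fabp2 and the hormone genes Gcg, Ins1 and Ins2 among the unmarked (Fisher's exact test, adjusted p = 0.632). Skeletal muscle genes were marked in 5 of 13 cases, Mylpf and Actn3 in domains shared with Tbc1d10b and Zdhhc24, and Myod1 (1.63 ± 0.0941 kb), Pax7 (1.06 ± 0.0693 kb) and Myf6 (0.252 ± 0.356 kb, replicate 1 alone) in their own; Acta1, Ckm, Myf5 and Myh3 were among the unmarked (Fisher's exact test, adjusted p = 0.0523, and 0.0220 without replicate 1). None of these 5 lists differed from CpG-matched lists (the anterior, neuron, heart and muscle lists had adjusted permutation p = 1, the gut list 0.801). The anterior list, fully marked against 98.4% in its matched lists, could not have been called above them.

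**Figure D2:**
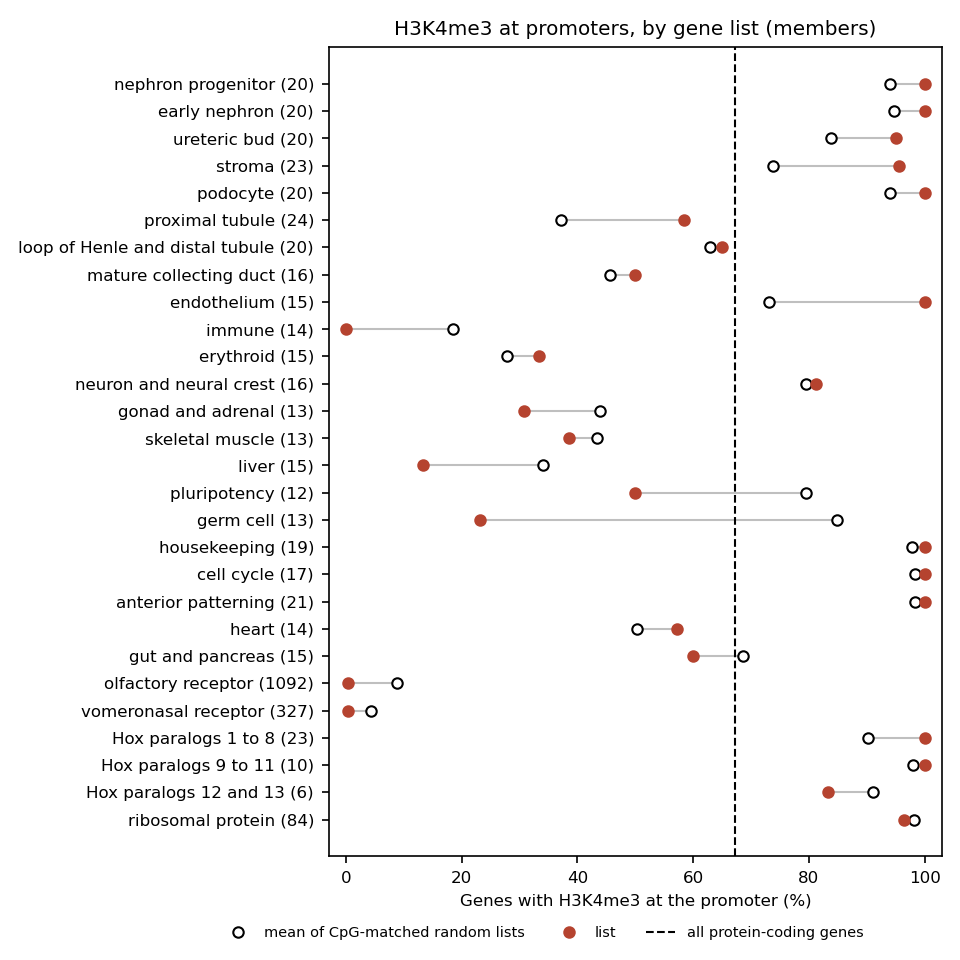
Percent of genes with H3K4me3 at the promoter in each of 28 gene lists (filled points, list sizes in parentheses) and the mean of 10000 random lists matched on promoter CpG content (open points); the dashed line is the share of all protein-coding genes. The germ cell list lay at 23.1% against 84.8% in its matched lists, and the endothelium list at 100% against 73.1%.

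Constitutively used genes and the Hox clusters were marked almost completely. All 19 housekeeping genes were marked, with Rpl13a (8.21 ± 0.276 kb, shared with Rps11), Rps18 (7.35 ± 0.551 kb, shared with B3galt4 and Vps52), Eef2 (6.11 ± 0.868 kb) and Ywhaz (5.26 ± 0.710 kb) the widest. All 17 cell cycle genes were marked, among them Mki67 (4.27 ± 0.114 kb), Mcm7 (4.06 ± 0.00707 kb, shared with Ap4m1), Cdk1 (3.93 ± 1.05 kb), Plk1 (3.87 ± 0.00990 kb), Mcm5 (3.80 ± 0.707 kb) and Pcna (3.66 ± 0.423 kb). Ribosomal protein genes were marked in 81 of 84 cases, among them Rps11, Rpl35 (7.04 ± 0.0389 kb, shared with Arpc5l) and Rpl23a (5.53 ± 4.03 kb, shared with Nek8 and Tlcd1), and the exceptions were Rpl10l, Rpl39l and Rpl3l, which encode variants of the common proteins. Fisher's exact test gave adjusted p = 0.00212, 0.00312 and 4.22e-10, and the lists did not differ from CpG-matched lists (adjusted permutation p = 1, 1 and 0.638). The housekeeping and cell cycle lists, fully marked against 97.8% and 98.4% in matched lists, could not have been called above them. The Hox genes specify position along the body. All 23 genes of paralog groups 1 to 8 and all 10 of groups 9 to 11 were marked, and 5 of 6 of groups 12 and 13 (Fisher's exact test, adjusted p = 0.000795, 0.0523 and 0.696). Against CpG-matched lists, the adjusted permutation p was 0.313, 1 and 1. Groups 1 to 8 and 9 to 11 were fully marked, so this comparison could not have called them above matched lists. Hoxb3, Hoxb4, Hoxb5 and Hoxb6 shared the domain of 57.9 kb with Hoxb7, and Hoxa9, Hoxa10 and Hoxa11 shared 48.9 ± 1.90 kb, so these genes were not independent. Hoxa13 (2.31 ± 0.0502 kb), Hoxc13 (1.62 ± 0.0509 kb), Hoxd13 (1.54 ± 0.406 kb) and Hoxb13 (1.03 ± 0.0686 kb) had narrow domains, and Hoxc12 had a peak in replicate 1 alone. Hoxd12 had 22.9 ± 30.2 kb: in replicate 1 a weak peak of 0.185 kb (enrichment value 2.11) between its peak and the large Hoxd domain joined them, and in replicate 2 they stayed apart. When the peak summit had to lie in the window, 69.6% of groups 1 to 8 were marked (Fisher's exact test, adjusted p = 0.891).

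**Figure D3:**
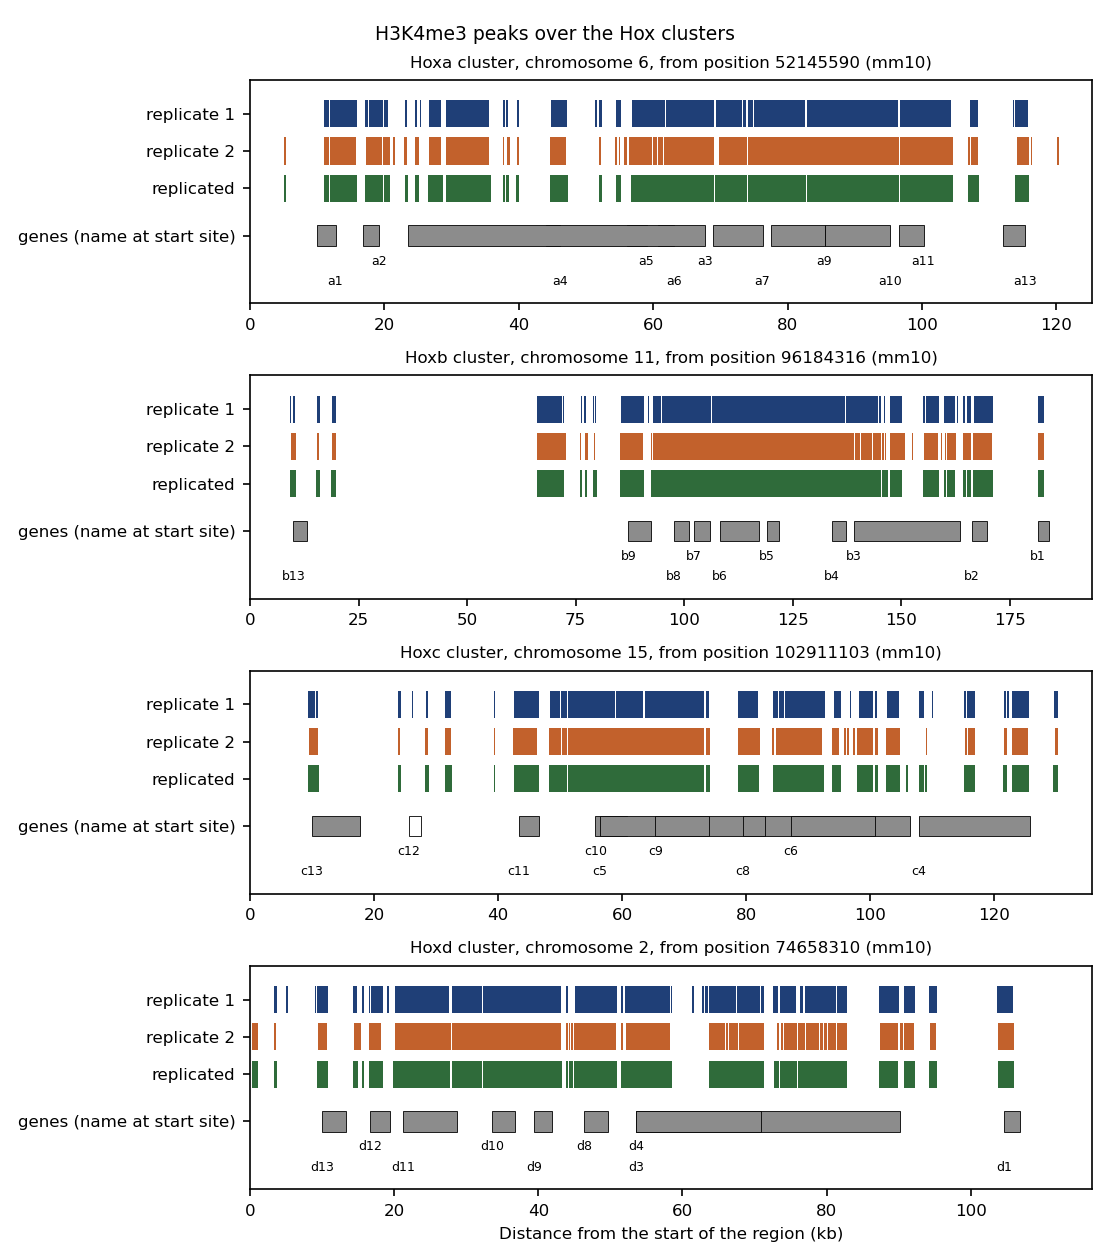
Map of the Hoxa, Hoxb, Hoxc and Hoxd clusters with H3K4me3 peaks of each replicate and of the replicated list (coloured bars) over the genes (boxes, grey for marked promoters and white for unmarked, numbered by paralog at the start site); the x axis is distance in kb. With peaks closer than 1000 bp joined, the widest domains were 57.9 kb in Hoxb, 47.8 kb in Hoxa, 38.7 kb in Hoxd and 25.97 kb in Hoxc.

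With peaks closer than 1000 bp joined, the 4 domains centred on Hoxb5, Hoxa9, Hoxd9 and Hoxc9 were wider than any other. These were Hoxb5 (57.9 kb, with Hoxb3, Hoxb4, Hoxb6, Hoxb7 and Hoxb8; chromosome 11, 96276612 to 96334508), Hoxa9 (47.8 kb, with Gm28308, Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa10 and Hoxa11; chromosome 6, 52202343 to 52250184), Hoxd9 (38.7 kb, with Hoxd3, Hoxd8, Hoxd10 and Hoxd11; chromosome 2, 74678095 to 74716802) and Hoxc9 (25.97 kb, with Hoxc10; chromosome 15, 102959357 to 102985329). This order depends on the joining: the widest single replicated peaks of these clusters were 53.1 kb in Hoxb, 22.0 kb in Hoxc, 12.3 kb in Hoxa and 10.96 kb in Hoxd, and the Gata3 domain of 21.8 kb was 1 peak. Next came Nr2f2, a nuclear receptor gene (25.7 kb; chromosome 7, 70345569 to 70371288), Gata3 (21.8 kb; chromosome 2, 9868676 to 9890492), Meis2 (19.4 kb; chromosome 2, 116053782 to 116073175) and Pax2 (19.3 kb; chromosome 19, 44745964 to 44765304). The others of the 20 widest were Emx2 (17.4 kb), Tbx3 (16.4 kb), Six2 (16.4 kb; chromosome 17, 85679584 to 85695992), Tbx2 (16.3 kb), Uncx (15.5 kb), Foxc1 (14.9 kb), the demethylase gene Kdm6b (14.6 kb), Zfp503 (14.6 kb), Prrt2 (14.5 kb, with Gm42742, Kif22, Maz, Mvp and Pagr1a in the same domain), Meis1 (14.4 kb), Irx5 (13.9 kb) and Bahcc1 (13.7 kb). These are widths in the replicated list, and in the replicates' own lists Foxc1 had 12.8 and 8.51 kb, and Zfp503 10.9 and 14.4 kb. Across all marked genes the median width was 2.39 kb, with an interquartile range of 1.77 to 3.21 kb, and 51 of 22778 domains were wider than 10 kb. Median widths were 5.17 kb in the nephron progenitor list, 5.44 kb in the early nephron list, 4.14 kb in the ureteric bud list and 4.90 kb in the stroma list, each at percentile 100 of 10000 random lists of marked genes. Podocyte, housekeeping and endothelium lists had medians of 3.87, 4.18 and 3.44 kb (percentiles 99.99, 100 and 99.4). Ribosomal protein and cell cycle genes had medians of 3.16 and 3.19 kb (percentiles 100 and 98.4). The proximal tubule (1.57 kb), mature collecting duct (1.33 kb), heart (1.23 kb) and gut and pancreas (1.36 kb) lists lay at percentiles 0.26, 0.33, 0.06 and 0.30. The distal tubule, neuron and anterior patterning lists, at 1.87, 2.14 and 2.15 kb, lay at percentiles 5.44, 22.0 and 17.8. When peaks up to 3000 bp apart were joined, anterior patterning moved to percentile 99.99, heart to 95.9 and gut and pancreas to 71.8. Against CpG-matched lists, proximal tubule moved to percentile 40.3 and mature collecting duct to 6.70, while heart (2.43) and gut and pancreas (0.06) stayed in the lower tail. Endothelium moved to 94.3 with no joining, cell cycle to 94.98 with joining up to 3000 bp, and distal tubule to 0.58 with no joining and 0.72 without replicate 2. Joining no peaks beyond overlap narrowed Tcf21 to 3.93 kb, Eya1 to 3.09 kb, Foxd1 to 2.93 kb and Myod1 to 0.696 kb, and joining up to 3000 bp widened Osr1 to 15.5 kb and Nphs1 to 4.22 kb.

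**Figure D4:**
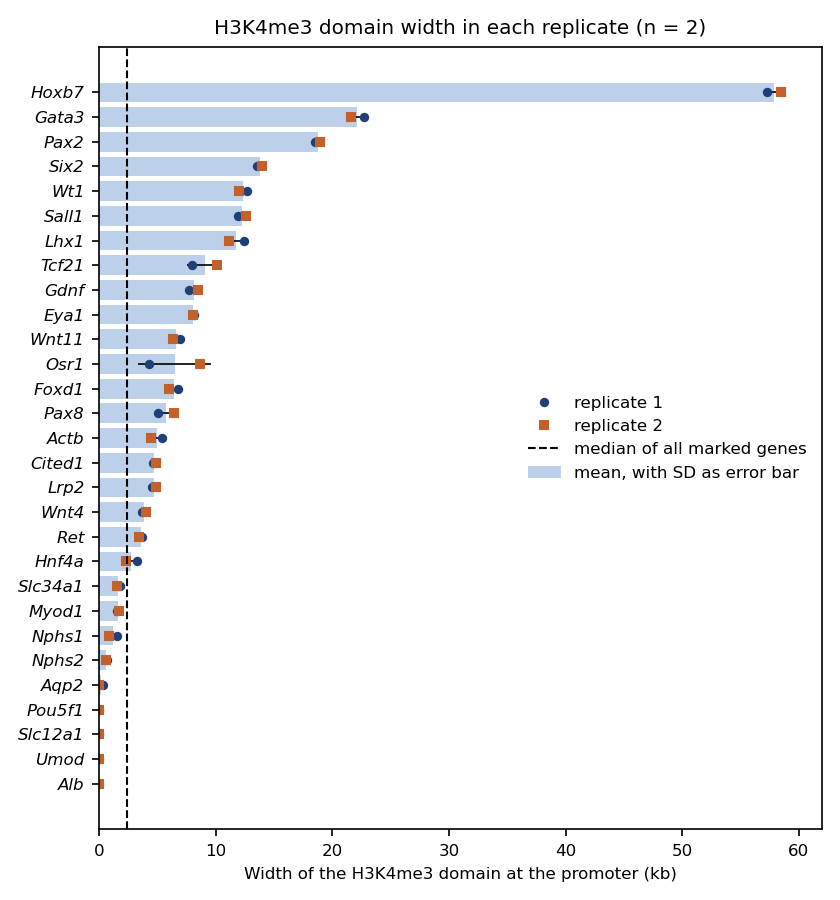
Width in kb of the H3K4me3 domain at the promoters of 29 genes chosen at the outset, in replicate 1 (circles) and replicate 2 (squares), with the mean as a bar and the SD as an error bar; the dashed line is the median of all marked genes, 2.39 kb. Alb, Pou5f1, Slc12a1 and Umod lay at 0 in both replicates, and Osr1 had the largest SD, 3.13 kb.

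Of the genes marked in the list of 1 replicate and not the other, 20 were in the fixed lists, and these were weakly marked. In replicate 1 alone these were Cubn, Hao2, Pck1, Clcnkb, Elf5, Aqp2, C1qa, Myf6, Barhl1 and Hoxc12, and in replicate 2 alone Aqp4, Csf1r, Laptm5, Tyrobp, Epb42, Gata1, Mc2r, Afp, Tbx5 and Vil1. Cubn, Elf5, Myf6 and Barhl1 were in the replicated list, and the other 16 were not. The highest enrichment values among them were 7.48 at Myf6 and 5.06 at Elf5 (replicate 1), against a median of 10.3 for all replicate 1 peaks. Over the 14609 genes marked in both replicates, the median domain width was 2.26 kb in replicate 1 and 2.35 kb in replicate 2, and widths differed by more than 2-fold in 202 genes (1.38%).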

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

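The tests for these results were chosen after the results were seen, except those on the separate list of nerve and glial genes and on CpG island length and start sites, whose bounds were set before their values were known; island-matched widths at other joining distances, and the nerve test with the mark required in each replicate, were also added after.

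Peaks that the authors called on both replicates together and left out of the replicated list entered the comparisons only with the joint list, as an alternative, and drew attention because they lay at promoters more often than random positions. Of 7180 such peaks on chromosomes, 1899 (26.5%) overlapped a promoter window, against a mean of 7.03% and a highest value of 7.74% in 100 random placements. They were weak, with a median enrichment value of 2.54 over all 7181. These peaks alone marked 170 genes, of which 15 were in the fixed lists: Afp, Amh, Aqp2, Aqp4, Atp6v1b1, Cd68, Clcnkb, Csf1r, Hao2, Hoxc12, Laptm5, Phox2b, Tbx5, Vil1 and Zfp42. Of the 170 genes, 70.0% had CpG-poor promoters. Only genes without a replicated promoter peak could be counted, and most of those were CpG-poor, so this share is no excess. The replicated list marked 783 of 6999 CpG-poor genes and 14674 of 21853 genes in all. Scaffolds that are not placed on a chromosome, also unused, held 11 replicated peaks on 6 scaffolds, with a median enrichment value of 12.1 and a highest of 45.7.

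Promoters of genes of the head, nerve, heart, muscle, gut and pancreas carried the mark in the kidney. CpG-rich members of these 5 lists were marked in 41 of 41 cases (100%), among them Foxg1, Otx2 and Pax6. CpG-poor members were marked in 4 of 23 (17.4%, Fisher's exact test, p = 1.02e-12). Over all protein-coding genes the shares were 98.7% and 11.2%, so this outcome was largely set by the genome-wide shares. Promoter CpG content stays a candidate explanation, without added support from this test. CpG-poor genes for main products of heart, muscle, gut, pancreas and liver, such as Myh6, Ins2, Acta1 and Alb, gave no sign of cells of those tissues. Of 30, 2 were marked, Actc1 and Myl2 (6.67%, Wilson 95% interval 1.85 to 21.3%), against 11.2% of other CpG-poor genes (Fisher's exact test, p = 0.572). This source needed a lower bound above 11.2%, and an upper bound under 50% was set against it as the main source. By these bounds the result counted against it. However, many of the genes had been seen unmarked, and liver genes such as Alb belong to none of the 5 lists. The interval also holds 11.2%, so a few such cells are not excluded. Nerve cells and glia stay open: a list of 27 of their genes, none of them in the fixed lists, was marked in 23 (85.2%) against 77.04% in CpG-matched lists (permutation p = 0.198), Elavl2 (4.46 ± 2.53 kb), Mapt (3.53 ± 0.197 kb) and Ngfr (3.27 ± 0.0898 kb) among them. CpG-poor nerve and glial genes of this list and the neuron list were marked in 4 of 9 cases (44.4%; Wilson 95% interval 18.9 to 73.3%), Dcx, Fabp7, Sox10 and Stmn2 and not Dbh, Plp1, S100b, Stmn4 or Th, against 11.1% of other CpG-poor genes (Fisher's exact test, p = 0.0123), which goes with such cells, but the values had been seen, Fabp7 lacked the mark in replicate 2, and with the mark required in each replicate's list too, 3 of 9 (33.3%) against 10.4% did not pass (Fisher's exact test, p = 0.0588). The design has 1 group, so no biological explanation was tested between groups.

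Domains at regulators of the embryonic kidney were wide, with medians of 4.14 to 5.44 kb in the nephron progenitor, early nephron, ureteric bud and stroma lists, against 2.39 kb for all marked genes. Neither CpG ratio nor CpG island length at the start sites, matched by decile, accounts for all of it: against lists matched on the ratio the lowest of the 4 lists lay at percentile 100, and against lists matched on island length at percentile 99.8 (ureteric bud, 4.14 against 2.78 kb). Random lists for these 4 had medians of 2.39 to 2.40 kb unmatched and 2.53 to 2.94 kb when matched on island length. Island length thus goes with a part of the width, and differences within a decile were not matched. With genes that share a domain left out and random lists matched on the number of start sites, the lowest lay at percentile 100. Anterior patterning genes, with longer islands (median 4.75 kb against 1.60 to 3.33 kb in the 4 lists), had narrower domains than lists matched on island length (2.15 against 3.42 kb, percentile 0.075), and with peaks up to 3000 bp apart joined they lay at percentile 29.4 of such lists (4.15 against 4.57 kb), while the lowest of the 4 kidney lists lay at 99.4. Wide domains were not particular to the kidney lists. Housekeeping and clustered histone genes, several in shared domains, had medians of 4.18 and 4.20 kb (percentile 100 of random lists for each). Forkhead and Sox genes had 3.05 and 3.43 kb (percentile 99.8 for each), while zinc finger and solute carrier genes lay at percentiles 0 and 0.01. Whether use of the kidney regulators in this tissue goes with wide domains stays open, as do read depth, the joining of nearby peaks by the peak caller and the choice of the lists by known function.

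CpG-rich promoters without the mark were rare, 147 of 11234, and this pattern was chosen for weighing after the names of the genes had been read. Repeated sequence, to which short reads cannot be placed uniquely, is a candidate explanation for part of them: 68 (46.3%; Wilson 95% interval 38.4 to 54.3%) had at least 50% of their promoter's 32-mers at more than 1 place in the genome, against 0.7% of 1000 marked CpG-rich genes (Fisher's exact test, p = 1.53e-59). These included 45 gene models named Gm, and Loxl2, Slc25a37 and Entpd4 on chromosome 14. By this measure it does not account for the alpha protocadherin and germ cell genes, of which 0 of 16 (0%, Wilson upper bound 19.4%) had such promoters. The alpha protocadherin promoters still had between 9.38% and 29.4% of their 32-mers at more than 1 place, so a smaller effect of repeats there is not excluded. Germ-line genes that lack the mark in body tissues may account for some of the other 79, since 5 of the 8 CpG-rich germ cell genes were unmarked (62.5%; Ddx4, Mael, Sycp1, Sycp3 and Tex11) against 1.26% of other CpG-rich genes (Fisher's exact test, p = 1.94e-08), but this list had been seen to be unmarked.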

How the results depend on the processing

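All alternatives here were planned before the data were examined. Over 10 of them, the number of marked genes ranged from 14101 to 14882, and at least 14101 of the 14674 genes stayed marked under each. Of 308 comparisons of a gene list under an alternative, 265 kept their direction and their side of the threshold, 14 passed it newly, 19 lost it and 10 turned round, 3 of which also crossed the threshold; the cause was not tested except where stated. The values that follow are differences in percentage points between a list and its background. Against CpG-matched lists, which remove the part of a call that promoter CpG content gives, calls ended for nephron progenitor (5.98), early nephron (5.29), ureteric bud (11.1), podocyte (6.05), housekeeping (2.19), cell cycle (1.62), anterior patterning (1.61), Hox 1 to 8 (9.76), immune (-18.5), gonad and adrenal (-13.1) and liver (-20.8). The nephron progenitor, early nephron, podocyte, housekeeping, cell cycle, anterior patterning and Hox 1 to 8 lists were fully marked, the highest share possible. For them the matched comparison could not have passed, so the end of these calls does not show that CpG content gave them. The immune list had no marked gene, the lowest share possible, and the same holds for it. The direction turned for proximal tubule (21.2), distal tubule (2.13), mature collecting duct (4.46), erythroid (5.54), heart (6.91), Hox 12 and 13 (-7.70) and ribosomal protein (-1.68). Of these, the erythroid and ribosomal protein calls also ended, and proximal tubule passed the threshold. At enrichment values of at least 5, calls were gained for proximal tubule (-32.2), mature collecting duct (-34.3), pluripotency (-32.2), heart (-37.0) and Hox 9 to 11 (34.5) and lost for anterior patterning (20.2). At −log10 p of at least 10, they were gained for mature collecting duct (-29.0), pluripotency (-33.2) and Hox 9 to 11 (33.5). With the joint peak list, the distal tubule (2.08) and mature collecting duct (0.824) lists turned round and the gonad call ended (-29.5). With peak summits, the ureteric bud (14.6) and Hox 1 to 8 (4.12) calls ended and a skeletal muscle call (-34.7) was gained. With the most upstream start site, the endothelium call ended (22.2) and pluripotency (-31.2) and Hox 9 to 11 (35.5) calls were gained. Skeletal muscle also passed with windows of 500 bp (-35.9) and the intersection of the replicates (-36.1), and the gonad call ended with windows of 2500 bp (-22.0). With each replicate left out in turn, the ranges were -34.0 to -20.8 for erythroid and -36.6 to -29.0 for gonad and adrenal, both lost without replicate 1. They were -36.7 to -28.9 for skeletal muscle, passed without replicate 1, and -2.42 to 2.68 for distal tubule, turned without replicate 2. Lists that kept both but moved included proximal tubule (-13.3 to -0.652), heart (-10.2 to -3.13) and gut and pancreas (-7.32 to -0.748). The share of replicated peaks at promoters, 66.7%, became 63.9% with windows of 500 bp, 74.4% with 2500 bp, 58.0% in the joint list, 61.1% to 61.3% with 1 replicate left out, 65.0% in the intersection, 79.0% at enrichment values of at least 5, 73.0% at −log10 p of at least 10 and 64.4% for summits. Peak overlap between replicates (replicate 1, then replicate 2) became 74.5% and 74.6% with 50% reciprocal overlap, 96.0% and 95.02% at enrichment values of at least 5, 96.0% and 95.7% at −log10 p of at least 10, and 95.9% and 94.7% for the 20000 strongest peaks; the stricter lists leave out the weak peaks that were least often shared. The Spearman correlation was 0.875 at promoters and 0.891 at enrichment values of at least 5 in both. The median of the 20 widest domains, 16.4 kb, was 11.5 kb with no joining (13 of the 20 genes shared) and 22.3 kb with joining up to 3000 bp (12 shared), by construction. Widths of named genes moved by more than their SD in 47 of 116 cases, and list width percentiles moved in 15 of 90. Read depth, which limits how many weak peaks each list can hold, is unknown. No paired analysis was possible because the series has 1 group.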

Other observations

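The 24 further gene groups below were chosen after the main results were seen, 3 of them after their members were seen, and adjusted p-values are over these 24; the features of peaks away from promoters had bounds set before they were computed.

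Of the further named groups, 3 had wider domains than random lists. All 16 genes of hedgehog and BMP signalling were marked, with a median width of 5.17 kb (percentile 100 of random lists): Id2 had 9.08 ± 0.0361 kb, Bmp7, which nephron progenitors need, 7.76 ± 0.0679 kb, Ptch1, the hedgehog receptor gene, 7.51 ± 0.152 kb, and Bmp4 6.003 ± 0.00778 kb (Fisher's exact test, adjusted p = 0.00440). All 20 polycomb and trithorax genes were marked, with Kdm6b at 15.1 ± 0.976 kb, Setd1b at 10.8 ± 0.104 kb and Cbx4 at 10.2 ± 0.961 kb (median 3.55 kb, percentile 99.9; Fisher's exact test, adjusted p = 0.00116). Of 16 imprinted genes (Dlk1 also in the stroma list) 15 were marked, with Igf2, a growth factor gene, at 11.1 ± 0.402 kb, Gnas at 9.61 ± 0.0820 kb and Grb10 at 6.12 ± 0.00212 kb, and Ndn unmarked (median 3.82 kb, percentile 99.9; Fisher's exact test, adjusted p = 0.0370). All 19 cyst and cilium genes were marked, with Glis2 at 5.91 ± 0.829 kb, Pkd1 at 3.59 ± 0.0446 kb and Pkd2 at 2.57 ± 0.0856 kb, and a median of 2.19 kb at percentile 24.4 (Fisher's exact test, adjusted p = 0.00167). In the renin and angiotensin group, of which the fixed lists also held Ren1 and Agtr2, 7 of 10 were marked, with Enpep at 4.27 ± 0.603 kb and the receptor gene Agtr1a at 1.41 ± 0.0453 kb, and Agt, Mas1 and Ren1 unmarked (Fisher's exact test, adjusted p = 1). None of these 5 groups differed in its marked share from CpG-matched lists (adjusted permutation p from 0.324 to 1), nor did nerve and glia (23 of 27, median width 1.99 kb at percentile 4.94, adjusted permutation p = 0.372). The hedgehog and BMP, polycomb and trithorax, and cyst and cilium groups were fully marked, so this comparison could not have called them above matched lists.

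Among gene families were the 3 clusters of protocadherins, adhesion proteins of neurons. None of the 12 alpha cluster entries named Pcdha and a number was marked, against 97.54% of CpG-matched lists. In the other clusters 6 of 22 beta genes (47.8% matched) and 20 of 21 gamma genes (86.0% matched) were marked. The difference between clusters was not tested. This alpha list was drawn after its members were seen and leaves out Pcdhac1 and Pcdhac2 of the same cluster, both marked. Its share of 0% depends on that choice. A Pcdha11 entry in the list had a promoter peak in replicate 2 alone. The adjusted permutation p was 0.0008 for alpha (from 0.0002, the smallest the draws can give), 0.160 for beta and 0.372 for gamma, and over all 57 clustered protocadherins 28 were marked (permutation p = 0.0002). The gamma gene Pcdhgc3 had a domain of 4.76 ± 0.594 kb. The alpha genes Pcdhac2 and Pcdhac1, outside the alpha list, had 1.75 ± 0.0156 and 0.461 ± 0.0283 kb. Collagen genes were marked in 37 of 44 cases against 61.5% in CpG-matched lists (permutation p = 0.0002), with Col4a1 and Col4a2 sharing 7.03 ± 0.139 kb and Col1a1 at 4.10 ± 0.571 kb. Zinc finger genes named Zfp were marked in 323 of 365 cases, above matched lists (81.4%, permutation p = 0.0002). Keratin and keratin-associated protein genes together, 9 of 110 (28.3% matched), and clustered histone genes, 59 of 67 (97.2% matched), lay below (permutation p = 0.0002 for each). Of the unmarked histone genes, Hist1h2ao, Hist1h2ap, Hist1h2bq and Hist1h2br had promoters with 100% of their 32-mers at more than 1 place in the genome, where short reads cannot be placed uniquely, and the test was not repeated without them. Among keratins Krt8 (2.41 ± 0.252 kb), Krt18 (2.08 ± 0.249 kb) and Krt19 (1.90 ± 0.134 kb) were marked. Groups with shares not different from matched lists were solute carriers (253 of 334), cytochrome P450 (26 of 100, with Cyp26b1 at 7.17 ± 0.0361 kb), UDP glucuronosyltransferases (2 of 22), beta-defensins (1 of 42), Wnt (18 of 19), Fgf (19 of 22), forkhead (40 of 44), Sox (18 of 19), T-box (10 of 13) and claudin (13 of 23) genes.

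Replicated peaks away from annotated promoters numbered 8596 (33.3%), with a median enrichment value of 4.85 and width of 603 bp. Strong ones lay in or near Zfp869 (76.2), Ppara (70.3), Pum2 (69.7), Pura (69.7) and Prdm2 (69.6). Those at Zfp869, Pura and Prdm2 lay at RefSeq start sites, and the peak near Ppara was 5.23 kb wide and lay 63.1 kb from that gene. Of the 8596 peaks, 10% lay within 1000 bp of a RefSeq start site, 11.7% had a CpG ratio over 0.6 and 30.4% lay within 5 kb of a promoter peak, against 2.13%, 0.321% and 5.49% of random positions. Each of these features had been set to account for the peaks at 50% or more, and each fell short; 4814 peaks (56.0%) had none of the 3. This pattern was tested before that of the unmarked CpG-rich promoters, which then took its place among the patterns weighed.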
